A study of Homo sapiens with 27 samples.

How the data were processed

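Gene expression was measured in BEAS-2B cells on 27 Affymetrix arrays, 3 for each of 9 groups: untreated cells and cells given indoor or outdoor airborne particles, each at 4, 10 and 24 h. Groups, times and replicate numbers were taken from the sample titles in the labels. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled for hybridization. The deposited values were on a log2 scale and, per the submitters' processing notes, were made by the authors with RMA in the affy package. RMA in general corrects background, normalizes arrays to a common distribution by quantiles and summarizes the probes of a probe set by median polish. Neither version is given in the sources used here. Values ran from 2.10 to 14.1, and array medians from 6.23 to 6.38. Because RMA had already aligned the arrays, a shift shared by most genes could not be seen in them. The number of arrays, 3 per group, limits the precision.

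The table held 22277 probe sets, of which 62 were controls. Through the platform annotation, 19064 of the others named 1 gene, 1043 named several and 2108 named none. Of the 19064, 19052 were found in the RefSeq gene table, which changed 0 symbols. Each gene was represented by the probe set with the highest mean over all arrays, giving 11963 genes, 4310 of them with several probe sets. The 3151 probe sets that were not controls and did not name 1 gene stayed out of the main gene counts. They were tested in a further fit of all probe sets that were not controls.

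Array names in the labels gave a series for each array. All 4 h arrays shared a series and all 10 h arrays shared another. At 24 h, the 3 arrays of replicate 1 came from a different series than the 6 arrays of replicates 2 and 3. The model in limma (version 3.58.1, R 4.3.3) was fitted with lmFit and eBayes to all 27 arrays with a mean for each group and, at 24 h, a term for the array series, leaving 17 residual degrees of freedom and adding 6.43 from the prior. All groups shared one estimate of the spread. Each of the 9 contrasts (indoor against untreated, outdoor against untreated and indoor against outdoor at 3 times) was tested two-sided, with Benjamini-Hochberg adjustment over the 11963 genes, and a gene was called at an adjusted p under 0.05. Moderated F tests in the same model asked whether a difference changed over the 3 times. Untreated cells over time served as background, since time and array series coincide there. Beta-actin and GAPDH control probe sets near the 3' and 5' ends of each transcript were used to compare RNA ends, with exact two-sided permutation tests between groups for beta-actin.

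Genes named in the text were set by a rule: in each contrast against untreated cells, the 12 largest increases and the 12 largest decreases among called genes whose 3 treated arrays all lay above, or all below, the 3 untreated ones; in each contrast of indoor against outdoor, the 6 largest each way. To these were added 16 genes whatever their result (CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, HMOX1, GCLM, TXNRD1, MT1X, MT2A, CXCL8, IL6, IL1B, CXCL1, HSPA1A and CDKN1A), and up to 4 members per gene list and contrast with the smallest p. AHRR and HSPA1A had no probe set naming them alone and were not analysed here. Other genes are said to be chosen after their values were seen.

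The 23 gene lists were aryl hydrocarbon receptor targets, NRF2 antioxidant targets, metallothioneins and zinc response, heat shock proteins, endoplasmic reticulum chaperones, ATF4 amino acid response, NF-kB cytokines and inflammatory genes, type I interferon response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, mitosis, DNA replication, p53 targets, immediate early and growth factor response, squamous differentiation, extracellular matrix and mesenchymal genes, matrix proteases and plasminogen system, mucus and airway secretory cells, ciliated cells, leukocyte and endothelial cells, complement and acute phase, ribosomal proteins, and oxidative phosphorylation. Each was tested with camera at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the lists within a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were the alternatives. Of the 23 lists, each contrast also has the number of members called over all genes and the number called when adjusted over the list alone.

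Replicate numbers were shared across groups in the labels. Deviations from group means of same-numbered arrays correlated over 0.1 in every pair for indoor against untreated at 10 h (0.12 to 0.13) and for the 3 contrasts at 24 h, where replicate 1 is also the other array series (indoor against untreated 0.1 to 0.35, outdoor against untreated 0.15 to 0.52, indoor against outdoor 0.26 to 0.55). In the other 5 contrasts at least 1 pair was lower. For indoor and outdoor responses, which share their untreated arrays, 100 simulations of unchanged groups against those arrays gave the correlation, covariance and overlap to set beside the observed values.

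The alternatives tried were no series term, replicates 2 and 3 alone at 24 h, the replicate number as a fixed or random block, each time fitted alone, an intensity trend or robust prior in eBayes, array weights, leaving out genes below the 40th percentile or the median of mean signal, the mean of all probe sets of a gene or every probe set, arrays centred on their medians, quantile normalization over all arrays, a 1.5-fold minimum, the beta-actin end difference as a covariate, leaving out the 10 h arrays, 24 h against 4 h alone, and leaving out each array in turn. The steps were tested on simulated data of 11963 genes with the spread of the real arrays. For indoor against untreated at 4 h, 49 of 50 genes changed 1.5-fold and 50 of 50 changed 2-fold were recovered, with 13 false calls among all genes; at 24 h the numbers were 48 of 50, 50 of 50 and 3. Camera recovered a simulated list of 30 genes shifted by 0.5 at both times, and called 2 and 5 of 100 unchanged lists at an unadjusted p under 0.05. The simulated genes varied independently and the lists were random, so these rates do not carry over to lists of correlated genes. Nor did the simulation hold a replicate that differed in direction from the others, as seen at 24 h. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.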

Results

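Gene expression was profiled in BEAS-2B, an immortalized line of human bronchial epithelial cells used at passage 41, after exposure to particulate matter from the air of a school. Cells were left untreated or received 10 µg/ml of PM10, the fraction of airborne particles small enough to be inhaled, collected indoors or outdoors. Each of the 9 groups (untreated, indoor and outdoor at 4, 10 and 24 h) was measured on 3 arrays, 27 in all. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The lowest correlation between replicates of a group, over all genes, was 0.9934, in indoor cells at 10 h. The median spread over genes within groups was 0.111 log2 units (SD) at 4 h, 0.147 at 10 h and 0.0965 at 24 h.

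The 10 h arrays differed from the others in signal along transcripts. The 3' probe set of beta-actin, a cytoskeletal gene used as a control, lay 2.04 to 2.99 log2 units above the 5' probe set on the 9 arrays at 10 h, against -0.21 to 0.0923 at 4 h and -0.139 to -0.0624 at 24 h. GAPDH, a glycolytic control gene, showed a 3' excess of 0.64 to 1.17 at 10 h. Within 10 h, the mean beta-actin difference was 2.63 ± 0.413 (SD, n = 3) in indoor, 2.37 ± 0.187 in untreated and 2.26 ± 0.234 in outdoor arrays. Indoor exceeded untreated by 0.257 (exact permutation p = 0.4) and outdoor by 0.364 (exact permutation p = 0.3), where 3 arrays against 3 cannot give a p below 0.1. For GAPDH the means at 10 h were 1.05 ± 0.12 in indoor, 0.758 ± 0.164 in untreated and 0.782 ± 0.0557 in outdoor arrays, with no test made. The lowest indoor array, at 0.929, lay above the highest outdoor one, at 0.846, and below the highest untreated one, at 0.945.

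**Figure D1:**
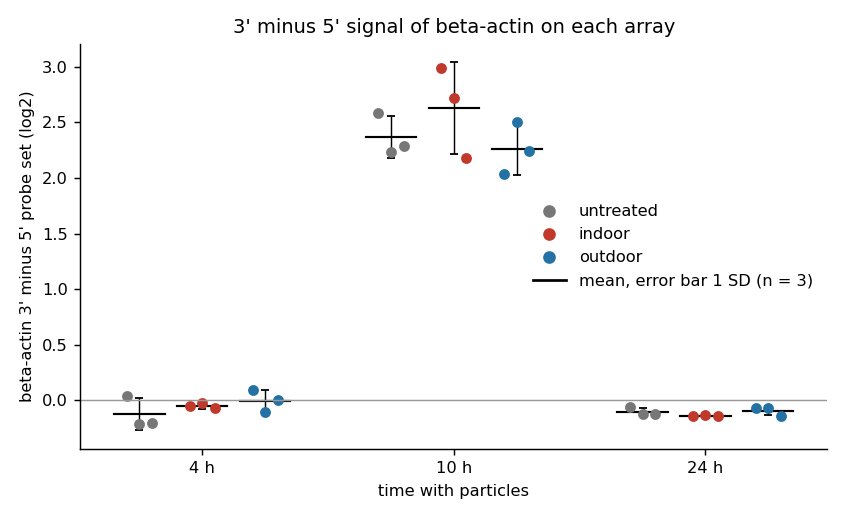
Difference between the 3' and 5' control probe sets of beta-actin (log2, vertical axis) on each of the 27 arrays, by time with particles and by treatment, with group means and SD (n = 3). The 9 arrays at 10 h lie between 2.04 and 2.99, and the arrays at 4 h and 24 h lie near 0.

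The first comparison asked which genes responded to indoor particles within 4 h. Genes of secreted inflammatory proteins rose most. CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose 9.41-fold (95% confidence interval 6.38 to 13.9), from a log2 level of 6.01 ± 0.25 in untreated to 9.25 ± 0.19 in indoor cells (SD, n = 3; limma, adjusted p = 2.43e-07). The neutrophil chemokines CXCL1, CXCL2, CXCL8, CXCL3, CXCL5 and CXCL6 rose by 2.66, 2.45, 2.34, 2.09, 1.94 and 1.57 on the log2 scale, with standard errors of 0.21 to 0.41 and adjusted p of 3.61e-05 to 0.000755. The cytokine IL6 rose 5.05-fold (3.26 to 7.82, adjusted p = 9.01e-05). Among other cytokines, IL24 rose by 1.62 ± 0.344 (log2 ± SE, adjusted p = 0.0201) and IL1A by 1.5 ± 0.308 (adjusted p = 0.0153). PTX3, a soluble pattern recognition protein, rose by 2.44 ± 0.277 (adjusted p = 2.02e-05), and TNFAIP3, a brake on NF-kB signalling, by 2.14 ± 0.258 (adjusted p = 3.61e-05). TIPARP and CYP1B1, targets of the aryl hydrocarbon receptor, rose by 1.26 ± 0.166 (adjusted p = 9.03e-05) and 1.22 ± 0.254 (adjusted p = 0.0168).

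Of the genes called after 4 h with indoor particles, 14 fell. The largest decreases were those of ANKRD1, by -0.80 ± 0.159 (log2 ± SE, n = 3, adjusted p = 0.0127), and of TXNIP, an inhibitor of thioredoxin and glucose uptake, by -0.73 ± 0.113 (adjusted p = 0.000728). ELAC1, ZNF556, LINC00963, WDR76, DRC9, SPAG8, ZNF682, LMCD1, RBM4B and RFC2 were lower by -0.57 to -0.35. Other probe sets of LINC00963 and SPAG8 did not all move the same way. Among the genes that rose, the other probe set of IL1A was at 0.05 and the lowest of CXCL5 at 0.09. Among the genes fixed in advance, CYP1A1, the classic aryl hydrocarbon receptor target, was at 1.79 ± 0.560 (adjusted p = 0.191), IL1B at 1.31 ± 0.329 (adjusted p = 0.0728) and the cell cycle inhibitor CDKN1A at 0.31 (adjusted p = 0.0836). The antioxidant genes HMOX1, NQO1, GCLM and TXNRD1 were at -0.03, 0.03, 0.10 and 0.26, and the metallothioneins MT1X and MT2A at 0.28 and 0.15, none of them called. In all, limma called 77 of 11963 genes, 63 higher and 14 lower. At an unadjusted p under 0.05 there were 1536. The 3 indoor arrays did not overlap the 3 untreated ones in 19.9% of genes, where chance gives 10%. The count depended on single arrays: it was 333 without untreated replicate 1, 47 without untreated replicate 2, 33 without untreated replicate 3, 44 without indoor replicate 1 and 36 without indoor replicate 2. It was 838 with array weights and 51 with a 1.5-fold minimum. The balance of directions depended on the fit too: 81.8% of the 77 genes were higher, against 55.3% of the 333 without untreated replicate 1 and 40.3% of the 838 with array weights. CCL20, IL6, PTX3, TNFAIP3, ICAM1, TIPARP, TXNIP and the CXCL chemokines named here passed under each of their 19 to 21 alternatives.

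The inflammatory genes moved as a group in indoor cells at 4 h. Of the 32 measured NF-kB cytokines and inflammatory genes, 23 rose and 26 did so when adjusted over the list alone. All 32 lay above untreated, with a median of 1.11 (camera, adjusted p = 1.58e-55, and adjusted p = 0.000959 with an estimated correlation). ICAM1, the leukocyte adhesion molecule of that list, rose by 1.34 ± 0.135 (log2 ± SE, adjusted p = 4.6e-06). Of 35 immediate early and growth factor genes, 3 rose, among them JUN by 0.60 and HBEGF, an EGF receptor ligand, by 0.96. Adjusted over the list alone, 11 rose and 1 fell (median 0.183, camera adjusted p = 4.64e-09, and adjusted p = 0.049 with an estimated correlation). DNA replication genes were lower, with 2 of 39 falling, RFC2 and the helicase component CDC45 (-0.32 ± 0.0702). Adjusted over the list alone, 8 fell (median -0.124, camera adjusted p = 4.64e-09, and adjusted p = 0.049 with an estimated correlation). Of 9 aryl hydrocarbon receptor targets, 3 rose (TIPARP, CYP1B1 and the growth factor EREG, by 1.08). When adjusted over the list alone, 6 rose, with a median of 0.245 (camera adjusted p = 5.22e-08, and adjusted p = 0.0568 with an estimated correlation). Of 10 metallothionein and zinc response genes, MT1M rose by 0.75 (adjusted p = 0.0491). In all 6 rose when adjusted over the list alone (median 0.259, camera adjusted p = 1.58e-05, and adjusted p = 0.119 with an estimated correlation).

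Camera called another 8 lists at 4 h with indoor particles, in none of which a gene was called over all genes by limma. Squamous differentiation (33 genes, median 0.132, adjusted p = 0.000116), in which SERPINB4 was at 1.07 and PI3 at 0.59, had 2 members higher when adjusted over the list alone. Matrix proteases and plasminogen system (19 genes, median 0.103, adjusted p = 0.00271), led by PLAU at 0.35, had 2, and complement and acute phase (14 genes, median 0.202, adjusted p = 0.00552), led by SERPINA3 at 1.11, had 1. Mitosis was lower (39 genes, median -0.0928, adjusted p = 0.000116), with CDC25C at -0.42 the 1 member adjusted over the list alone. Ribosomal proteins (26 genes, median 0.093, adjusted p = 7.28e-05) and oxidative phosphorylation (39 genes, median 0.173, adjusted p = 0.00193) had 0 members adjusted over the list alone, as did mucus and airway secretory cells (18 genes, median 0.143, adjusted p = 0.01). Extracellular matrix and mesenchymal genes (34 genes, median 0.0645, adjusted p = 0.0428) had 2 higher and 1 lower. With an estimated correlation the adjusted p of these 8 lists ran from adjusted p = 0.0846 for squamous differentiation to adjusted p = 0.358 for oxidative phosphorylation. Without untreated replicate 2 oxidative phosphorylation (adjusted p = 0.868), ribosomal proteins (0.22), mucus (0.22) and matrix proteases (0.0804) did not pass, nor mucus (0.085) and complement (0.0636) without indoor replicate 1, complement (0.0541) and extracellular matrix (0.0628) without untreated replicate 3, and extracellular matrix without untreated replicate 1 (0.281) or indoor replicate 2 (0.0791). With genes below the 40th percentile of signal left out, squamous differentiation did not pass (0.194). Not called at 4 h were hypoxia and glycolysis and heat shock proteins (adjusted p = 0.567 each), NRF2 antioxidant targets (0.52), type I interferon response (0.813), cholesterol and fatty acid synthesis (0.761) and ciliated cells (0.169). Nor were ATF4 amino acid response (0.761), endoplasmic reticulum chaperones (0.398), p53 targets (0.704) and leukocyte and endothelial cells (0.239). These last 4 were called in none of the 9 contrasts, with smallest adjusted p of 0.103, 0.103, 0.111 and 0.0823.

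**Figure D2:**
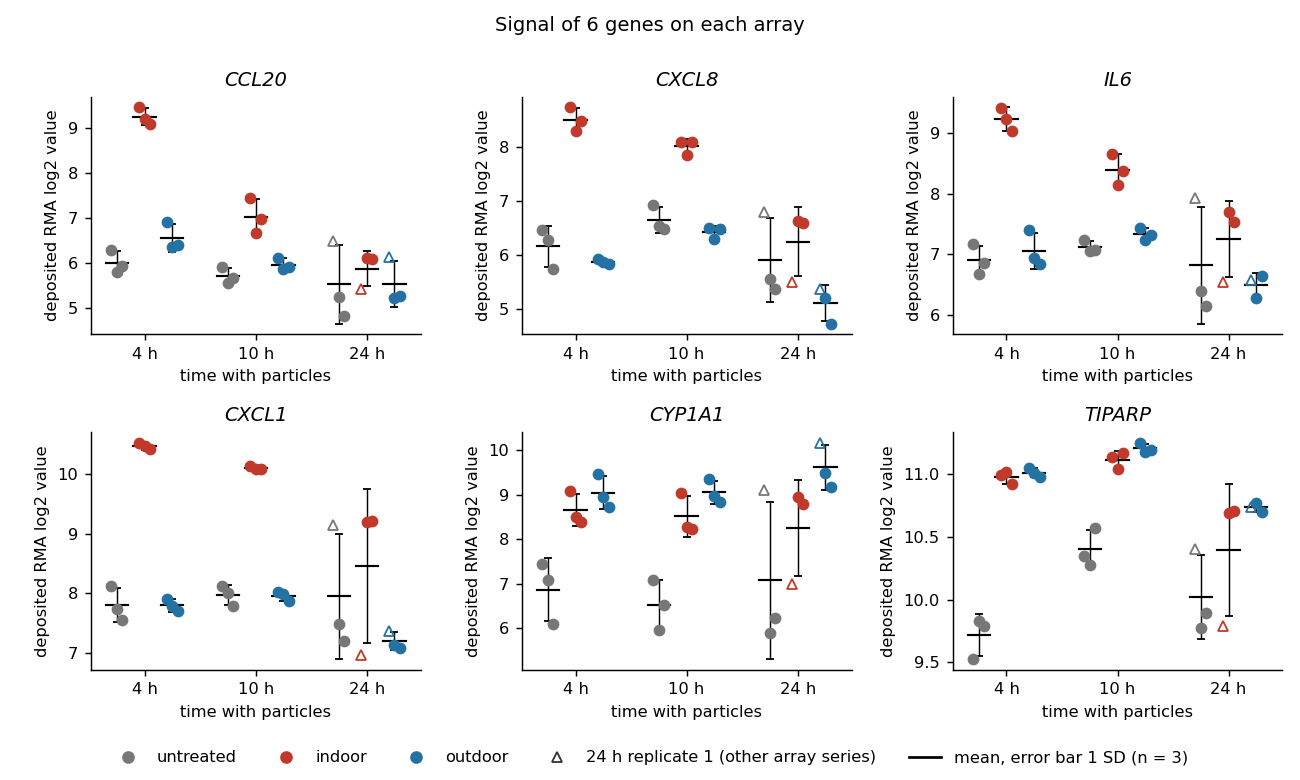
Deposited RMA log2 values (vertical axis) of 6 genes on each array, by time with particles and by treatment, with group means and SD (n = 3); open triangles are the 24 h arrays of replicate 1, from another array series. CCL20 is at 9.25 in indoor and 6.01 in untreated cells at 4 h, and TIPARP lies 2.45-fold above untreated in outdoor cells at 4 h.

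The next comparison asked which genes responded to outdoor particles within 4 h. TIPARP, an ADP-ribosyltransferase that represses the aryl hydrocarbon receptor, rose 2.45-fold (95% confidence interval 1.94 to 3.11; log2 1.30 ± 0.166 SE, n = 3; limma, adjusted p = 0.000678). CYP1A1, which oxidizes polycyclic aromatic hydrocarbons, was 4.52-fold above untreated with an interval of 2.02 to 10.1 and did not pass the adjustment (adjusted p = 0.825). Its relative CYP1B1 was at 1.06 ± 0.254 (adjusted p = 0.705) and the cytokine IL24 at 1.30 ± 0.344 (adjusted p = 0.825). The inflammatory genes CXCL8, IL6, CXCL1 and CCL20 were at -0.29, 0.16, -0.00 and 0.55, with adjusted p of 0.825 to 0.999. TIPARP was the only gene called of 11963 and passed under each of 21 alternatives, and 708 had an unadjusted p under 0.05. The count was 30 without untreated replicate 1, 8 with replicates 2 and 3 alone at 24 h, 5 with each time fitted alone and 2 with array weights.

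As a group, all 9 aryl hydrocarbon receptor targets lay above untreated in outdoor cells at 4 h, with a median of 0.251. Over all genes 1 rose, and 4 when adjusted over the list alone (camera, adjusted p = 3.73e-08, and adjusted p = 0.151 with an estimated correlation). DNA replication genes, such as CDC45 at -0.23, had 0 members called and a median of -0.109 (camera adjusted p = 3.98e-07, and adjusted p = 0.151 with an estimated correlation). Camera also placed ribosomal proteins such as RPS27 (0.40), oxidative phosphorylation genes such as NDUFB3 (0.42) and metallothioneins such as MT1M (0.51) above the other genes, with 0 members called (adjusted p = 1.78e-06, 6.9e-06 and 1.82e-05). These had adjusted p = 0.335, 0.335 and 0.245 with an estimated correlation, and adjusted p = 0.207, 0.305 and 0.0952 without untreated replicate 2. NF-kB cytokines and inflammatory genes had a median of 0.0898 with 0 members called and 1 adjusted over the list alone (adjusted p = 0.00472, and adjusted p = 0.653 with an estimated correlation). Hypoxia and glycolysis, whose member NDRG1 was at 1.07, and heat shock proteins were lower with medians of -0.104 and -0.0666 (adjusted p = 0.017 each, and adjusted p = 0.621 and 0.335 with an estimated correlation). Immediate early, squamous differentiation and mitosis lists passed at adjusted p = 0.0279, 0.0426 and 0.0468 and had adjusted p = 0.607, 0.513 and 0.728 with an estimated correlation. Single arrays ended other calls: the inflammatory list and hypoxia without untreated replicate 1 (adjusted p = 0.0742 and 0.166), hypoxia without outdoor replicate 2 (0.304), and heat shock proteins without outdoor replicate 1 (0.324) or untreated replicate 2 (0.296). Mitosis was at adjusted p of 0.0663 to 0.634 without outdoor replicates 1 or 2 or untreated replicates 2 or 3, squamous differentiation at 0.0663 to 0.291 without outdoor replicate 1 or untreated replicates 2 or 3, and immediate early genes at 0.105 to 0.391 without outdoor replicate 3 or untreated replicates 1 or 3. With genes below the 40th percentile of signal left out, heat shock proteins (0.132), hypoxia (0.21), mitosis (0.298) and squamous differentiation (0.73) did not pass, and with the beta-actin covariate mitosis and squamous differentiation did not (0.15 each).

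Indoor and outdoor particles were then compared directly at 4 h. CCL20 was higher with indoor particles by 2.69 ± 0.272 (log2 ± SE, n = 3; limma, adjusted p = 3.14e-06) and CXCL1 by 2.66 ± 0.410 (adjusted p = 0.00094). The others were CXCL8 by 2.63 ± 0.283 (adjusted p = 6.98e-06), PTX3 by 2.56 ± 0.277 (adjusted p = 6.98e-06), CXCL2 by 2.35 ± 0.356 (adjusted p = 0.000787) and IL6 by 2.17 ± 0.306 (adjusted p = 0.0003). TXNIP was lower by -0.69 ± 0.113 (adjusted p = 0.00169). Targets of the aryl hydrocarbon receptor were not called: the indoor-to-outdoor fold was 0.764 for CYP1A1 (95% confidence interval 0.342 to 1.7) and 0.976 for TIPARP (0.77 to 1.24), intervals that leave room for a difference in either direction. Limma called 36 genes, 35 higher and 1 lower with indoor particles, against 379 at an unadjusted p under 0.05. Of the 35, 33 were also called higher than in untreated cells, a comparison with the same indoor arrays, where independent lists would share 0.184. The count was 72 with array weights, 23 without indoor replicate 1 and 22 without outdoor replicate 2.

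Of the 32 NF-kB cytokines and inflammatory genes, 19 were higher with indoor than with outdoor particles at 4 h and 23 when adjusted over the list alone (median 0.877, camera adjusted p = 4.37e-89, and adjusted p = 5.29e-05 with an estimated correlation), ICAM1 among them at 1.35. The 35 immediate early and growth factor genes, with EREG at 0.78 and HBEGF at 0.80, had 0 members called and 2 adjusted over the list alone (median 0.12, camera adjusted p = 9.32e-10, and adjusted p = 0.0462 with an estimated correlation). Squamous differentiation had 1 member called, SERPINB4 at 1.25 (adjusted p = 0.0424; list adjusted p = 0.00285, and adjusted p = 0.176 with an estimated correlation). Hypoxia and glycolysis, matrix proteases such as PLAU (0.39), complement, extracellular matrix and mucus lists were higher, and mitosis and DNA replication lists lower, at camera adjusted p of 0.000121 to 0.0412. All had 0 members called and adjusted p = 0.0753 to 0.444 with an estimated correlation. Without indoor replicate 1 squamous differentiation (adjusted p = 0.228), hypoxia (0.141), mitosis (0.0772) and mucus (0.297) did not pass. Nor did mitosis without outdoor replicate 3 (0.771), DNA replication without indoor replicate 3 (0.243) or outdoor replicate 1 (0.0613), and mucus without indoor replicate 2 or outdoor replicates 2 or 3 (0.0981 to 0.343). With genes below the 40th percentile left out, squamous differentiation (0.146) and DNA replication (0.0602) did not pass.

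**Figure D3:**
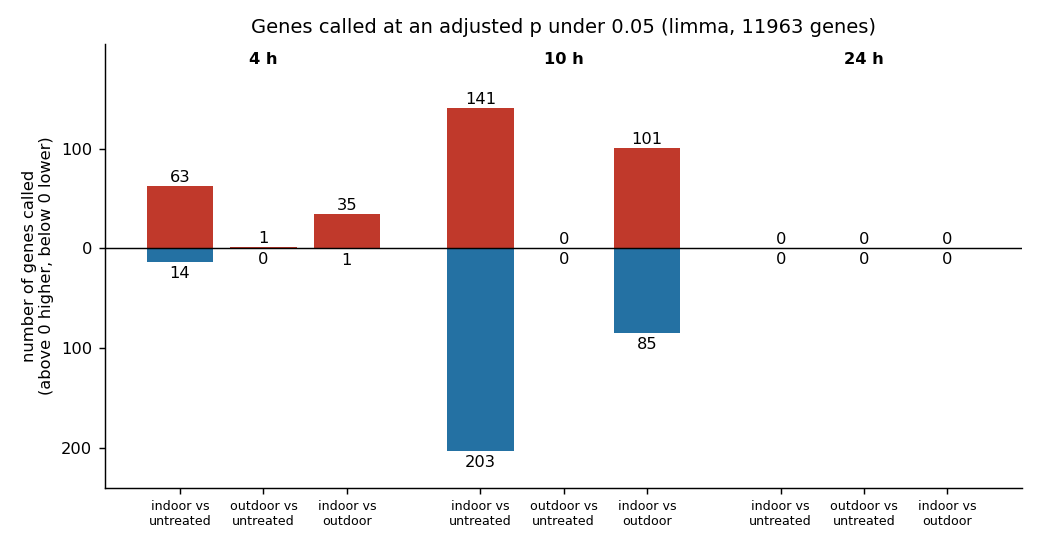
Number of genes called by limma at an adjusted p under 0.05 (vertical axis, higher above 0 and lower below 0) in each of the 9 contrasts, of 11963 tested. Indoor particles gave 77 genes at 4 h and 344 at 10 h against untreated cells, outdoor particles 1 and 0, and no gene was called at 24 h. The model shared 1 spread over all times and the counts depended on the fit, so they do not by themselves show a response that grew from 4 h to 10 h.

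After 10 h with indoor particles inflammatory genes led the increases among called genes. CXCL1 rose by 2.13 ± 0.410 (log2 ± SE, n = 3; limma, adjusted p = 0.00834), CXCL2 by 1.76 ± 0.356 (adjusted p = 0.011) and CXCL5 by 1.40 ± 0.273 (adjusted p = 0.00834). Next came CXCL8 at 1.37 ± 0.283 (adjusted p = 0.0122), CCL20 at 1.32 ± 0.272 (adjusted p = 0.0122) and IL6 at 1.28 ± 0.306 (adjusted p = 0.0252). CXCL3, PTX3, SERPINB4, TNFAIP3, NPTX1 and CXCL6 rose by 1.32, 1.18, 1.15, 1.04, 1.01 and 0.93. HMOX1, which degrades haem under oxidative stress, rose by 0.43 ± 0.107 (adjusted p = 0.0326), and TIPARP by 0.72 ± 0.166 (adjusted p = 0.0231). SCEL, a protein of cornifying epithelium, fell by -0.98 ± 0.266 (adjusted p = 0.0453). PLSCR4, the sulfate transporter SLC26A2, the interferon-induced IFI44L, the selenium carrier SELENOP, ZNF124, the vesicular amine transporter SLC18A2, TM6SF1, GIPC2, EML1, PTCD2 and ZNF91 were lower by -0.96 to -0.76. The other probe set of EML1 was at -0.09 and the lowest of CXCL5 at 0.03. CYP1A1 was at 1.99 ± 0.560 (adjusted p = 0.0525) and CYP1B1 at 0.84 (adjusted p = 0.0699). IL1B was at 0.87, NQO1 at 0.20, GCLM at 0.24, TXNRD1 at 0.21, CDKN1A at 0.15, MT1X at 0.00 and MT2A at 0.03, with adjusted p of 0.139 to 0.991.

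Limma called 344 genes at 10 h, 141 higher and 203 lower than in untreated cells, and 2334 had an unadjusted p under 0.05. Most changes were small: the median was 0.437 among the higher and -0.443 among the lower genes, and 60 of the 344 reached 1.5-fold. All of these arrays carried the 3' excess of beta-actin given for 10 h. The model shared 1 spread over all times. Within groups at 10 h the median spread was 1.32 times that at 4 h, so its p-values at 10 h may be too small. The count was 142 with the beta-actin excess as a covariate, 34 with 10 h fitted alone, 23 with array weights and 172 with no series term. It was 71 without indoor replicate 2, 546 without indoor replicate 3, and 226, 167 and 116 without untreated replicates 1, 2 and 3. With each array centred on its median, the share of higher genes moved from 41% to 59.2%. Of the genes named at 10 h, GIPC2 and ZNF124 passed under each of 18 alternatives, while HMOX1, IL6 and SCEL among others did not pass with the beta-actin covariate.

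Of the 32 NF-kB cytokines and inflammatory genes, 12 rose after 10 h with indoor particles and 22 when adjusted over the list alone, with a median of 0.501 (camera adjusted p = 1.32e-14, and adjusted p = 0.298 with an estimated correlation). Of the 9 aryl hydrocarbon receptor targets, TIPARP, EREG (0.74, adjusted p = 0.0446, and 0.0587 with a replicate block) and the amino acid transporter SLC7A5 (0.36) rose. The number was 5 when adjusted over the list alone (median 0.365, camera adjusted p = 0.00145, and adjusted p = 0.4 with an estimated correlation). Cholesterol and fatty acid synthesis had 3 of 24 members higher, LSS (0.41), FASN (0.45) and SQLE (0.27). Adjusted over the list alone, 7 rose and 1 fell (median 0.107, camera adjusted p = 0.00347, and adjusted p = 0.298 with an estimated correlation). Interferon response genes were lower, 6 of 43 falling, among them IFI44L (-0.86), IFIT1 (-0.75), IFI44 (-0.64) and DDX60 (-0.49). Adjusted over the list alone, 9 fell and 3 rose (median -0.14, camera adjusted p = 0.00748, and adjusted p = 0.493 with an estimated correlation). DNA replication (0 called, median -0.0719, camera adjusted p = 0.019, and adjusted p = 0.493 with an estimated correlation) was lower. The list of 10 ciliated cell genes was higher, with 1 member, TPPP3, called at 0.32 and 2 adjusted over the list alone (median 0.173, camera adjusted p = 0.0491, and adjusted p = 0.4 with an estimated correlation). The p53 targets DDB2 (-0.58), ZMAT3 (-0.43) and PPM1D (-0.36) fell in a list that camera did not call (adjusted p = 0.111). Complement and acute phase was not called (adjusted p = 0.103) and passed with a replicate block (adjusted p = 0.0477). Calls ended for the interferon list without indoor replicates 2 or 3 or untreated replicate 1 (adjusted p = 0.0667 to 0.126), for DNA replication without indoor replicate 3 or untreated replicates 1 or 2 (0.0654 to 0.148), and for ciliated cells without indoor replicate 3 or untreated replicates 2 or 3 (0.109 to 0.148). DNA replication also ended with genes below the 40th percentile left out (0.0588). The call of ciliated cells also ended with arrays centred on their medians and with replicates 2 and 3 alone at 24 h.

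With outdoor particles at 10 h no gene was called. CYP1A1 was 5.79-fold above untreated (95% confidence interval 2.59 to 12.9; log2 2.53 ± 0.560 SE, n = 3; limma, adjusted p = 0.105), TIPARP at 0.80 (adjusted p = 0.0953), CYP1B1 at 0.99 (adjusted p = 0.172) and IL24 at 1.06 (adjusted p = 0.315). CXCL8, IL6 and CXCL1 were at -0.22, 0.21 and -0.01. Limma called 0 genes, with 1004 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0647. Camera called 5 lists. Aryl hydrocarbon receptor targets were higher (0 called and 4 adjusted over the list alone, median 0.297, adjusted p = 3.75e-07, and adjusted p = 0.253 with an estimated correlation). DNA replication and type I interferon response were lower (medians -0.0656 and -0.0699, adjusted p = 0.00542 and 0.0399, and adjusted p = 0.635 and 0.802 with an estimated correlation). Ciliated cells and NRF2 antioxidant targets were higher (adjusted p = 0.0347 and 0.0399, and adjusted p = 0.415 and 0.635 with an estimated correlation). In the NRF2 list GCLM was at 0.33 and TXNRD1 at 0.28, and 3 genes were higher when adjusted over the list alone. The last 4 of these lists each lost the call without single arrays: DNA replication and interferon without outdoor replicates 2 or 3 or untreated replicate 1 (adjusted p = 0.0703 to 0.119 and 0.198 to 0.647), NRF2 without outdoor or untreated replicates 2 or 3 (0.0837 to 0.205), and ciliated cells without any outdoor array or untreated replicates 2 or 3 (0.0538 to 0.125). The interferon call also ended with the beta-actin covariate (0.0938), with no series term (0.0665) and with genes below the 40th percentile left out (0.107). The count of called genes was 24 without outdoor replicate 2, 13 without untreated replicate 1 and 1 without outdoor replicate 1. It was 8 with replicates 2 and 3 alone at 24 h, 4 with 10 h alone, 3 after quantile normalization, 2 with the beta-actin covariate and 1 with every probe set tested.

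Set against outdoor particles at 10 h, indoor particles gave higher CXCL1 by 2.15 ± 0.410 (log2 ± SE, n = 3; limma, adjusted p = 0.0147) and CXCL8 by 1.59 ± 0.283 (adjusted p = 0.0128). CXCL5 was higher by 1.47, CXCL6 by 1.16, CXCL3 by 1.10 and CCL20 by 1.06 (adjusted p = 0.0476). PMCH, a neuropeptide precursor, was lower by -0.97 ± 0.241 (adjusted p = 0.0429), as were the folate receptor FOLR1 (-0.84), SLC18A2 (-0.82), ZNF124 (-0.68), TRAPPC10 (-0.67) and the copper transporter ATP7A (-0.67). Other probe sets of CXCL5, FOLR1 and ATP7A did not all move the same way. CYP1A1 differed by -0.54 (adjusted p = 0.63). Of 186 called genes, 85 were lower with indoor particles and the rest higher, and 2270 had an unadjusted p under 0.05. With indoor against untreated they shared 38 higher and 46 lower genes and the indoor arrays, where independent lists would share 1.19 and 1.44. NF-kB cytokines had 7 of 32 members higher and 17 when adjusted over the list alone (median 0.412, camera adjusted p = 3.66e-10, and adjusted p = 0.426 with an estimated correlation). Cholesterol synthesis had 2 of 24, SQLE (0.33) and LSS (0.39), and 4 adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.426 with an estimated correlation). Hypoxia and protease lists passed at adjusted p = 0.0145 each and had adjusted p = 0.853 and 0.426 with an estimated correlation. Cholesterol synthesis did not pass without outdoor replicate 2 (adjusted p = 0.0705), proteases without indoor replicate 3 (0.0698), and hypoxia without indoor replicates 1 or 3 or outdoor replicate 2 (0.105 to 0.19). The count was 78 with no series term, 11 with 10 h alone, 0 with array weights, 32 at 1.5-fold and 5 with the beta-actin covariate. It was 21 without indoor replicate 2, 588 without indoor replicate 3, 393 without outdoor replicate 2 and 26 without outdoor replicate 3. The share of higher genes moved from 54.3% to 70.2% with centred arrays.

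**Figure D4:**
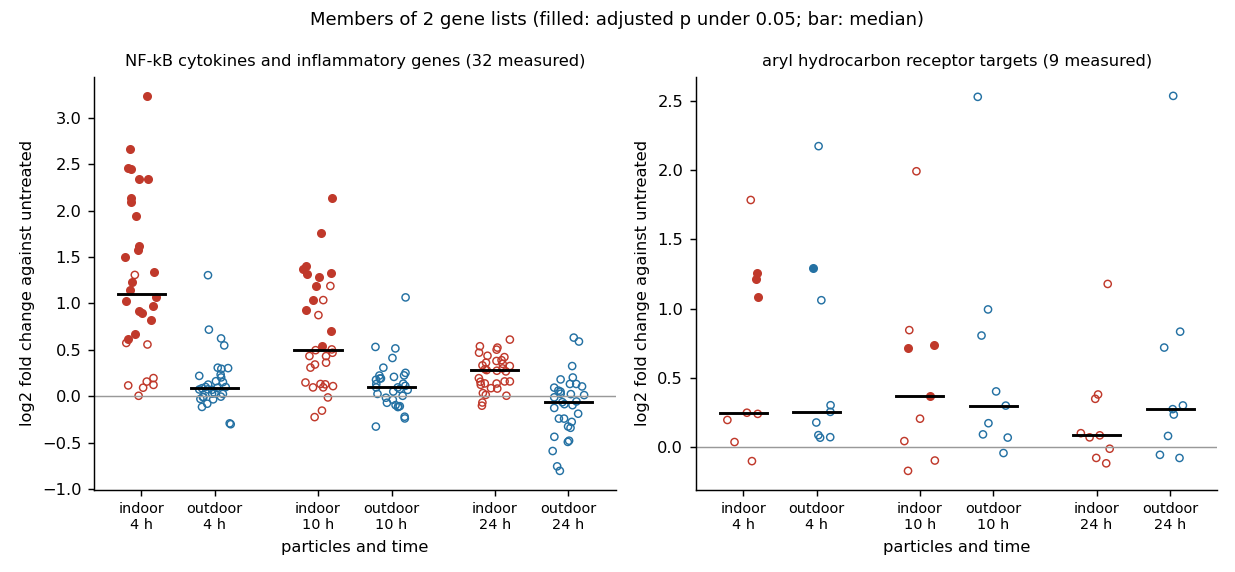
Log2 fold change against untreated cells (vertical axis) of each measured member of 2 gene lists, by particle source and time; filled points passed an adjusted p of 0.05 and bars are medians. The inflammatory list has a median of 1.11 with indoor particles at 4 h and 0.501 at 10 h; the aryl hydrocarbon receptor list has medians of 0.245 and 0.251 with indoor and outdoor particles at 4 h.

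At 24 h no gene was called in any of the 3 comparisons. CYP1A1 was at 8.26 ± 1.09 (log2 mean ± SD, n = 3) on arrays labelled indoor and 7.08 ± 1.77 on arrays labelled untreated (limma, adjusted p = 1), and 5.82-fold above untreated on outdoor arrays (95% confidence interval 2.61 to 13, adjusted p = 0.962). TIPARP was at 0.38 with indoor and 0.72 with outdoor particles (adjusted p = 1 and 0.962) and CYP1B1 at 0.35 and 0.83. CXCL8 was at 0.33, IL6 at 0.44, CXCL1 at 0.50, IL1B at 0.61 and CCL20 at 0.35 with indoor particles, and CXCL8 at -0.80 and CXCL1 at -0.75 with outdoor particles. HMOX1 and NQO1 were at 0.17 and 0.07 with indoor particles, and NQO1 at 0.27 with outdoor particles. Indoor exceeded outdoor by 1.14 for CXCL8 and 0.48 for ICAM1 (adjusted p = 1). Limma called 0 genes in each contrast, with 284, 366 and 293 genes at an unadjusted p under 0.05 for indoor against untreated, outdoor against untreated and indoor against outdoor, below the 598.2 that chance gives.

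Within the 2 array series at 24 h, the pair of indoor and untreated arrays of replicate 1 differed in the opposite direction to the pairs of replicates 2 and 3. CXCL1 was 1.85 higher on the arrays labelled indoor than on those labelled untreated in replicates 2 and 3 and lay at -2.18 in replicate 1. CYP1A1 was at 2.82 and -2.10, CXCL2 at 1.63 and -1.85, and CXCL8 at 1.14 and -1.29. CYP1A1 itself measured 9.11 on the array labelled untreated and 7.01 on the array labelled indoor in replicate 1, against 6.06 and 8.88 in the mean of replicates 2 and 3. Relative to the outdoor array of the same series, CYP1A1 in replicate 1 was at -3.17 on the array labelled indoor and -1.07 on the array labelled untreated, where replicates 2 and 3 had -0.46 for indoor and -3.28 for untreated. CXCL1 was at -0.40 and 1.78 in replicate 1, against 2.09 for indoor and 0.24 for untreated in replicates 2 and 3. Replicates 2 and 3 alone gave 26 called genes for indoor against untreated, all higher and 15 of them in the inflammatory list. They gave 5 for outdoor against untreated (CYP1A1, CYP1B1, TIPARP, IL24 and NPTX1) and 10 for indoor against outdoor. These genes were chosen after their values were seen. The replicate 1 array labelled indoor was below the one labelled untreated for all 26, with a median of -1.05. The difference between the 2 series in the indoor response was itself called for 32 genes, 16 of them inflammatory (limma with a mean for each group and series, 681 at an unadjusted p under 0.05). Replicate 1 has a single array per group, so that this test takes its spread from the other groups (15 residual degrees of freedom) and assumes that these single arrays vary like them. Without the replicate 1 array labelled indoor, the count was 7 for indoor against untreated and 12 for indoor against outdoor. Without the one labelled untreated it was 1 for indoor against untreated and 5 for outdoor against untreated. With array weights, outdoor against untreated gave 3 and indoor against outdoor 2.

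**Figure D5:**
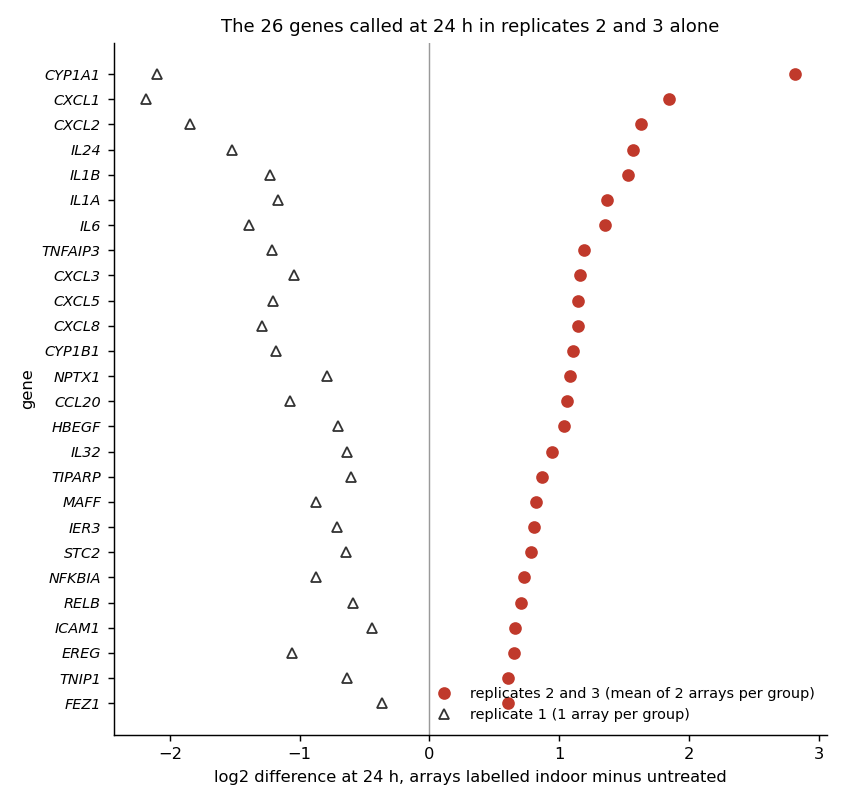
Log2 difference at 24 h between arrays labelled indoor and untreated (horizontal axis) for the 26 genes called in replicates 2 and 3 alone; filled points are means of replicates 2 and 3 and open triangles the single pair of replicate 1. The filled points are all above 0 and the triangles all below 0, with CYP1A1 at 2.82 and -2.10.

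Gene lists at 24 h were tested over all arrays. Camera called NF-kB cytokines higher on arrays labelled indoor than untreated (0 members called and 0 adjusted over the list alone, median 0.279, adjusted p = 4.35e-08, and adjusted p = 0.891 with an estimated correlation). The call ended without untreated replicate 2 (adjusted p = 0.295), untreated replicate 3 (0.0876) or indoor replicate 3 (0.319). Within series the list's median was 0.683 in replicates 2 and 3 and -0.529 in replicate 1. In the refits with replicates 2 and 3 alone, chosen for lists after the data were seen, camera used the preset correlation only. It called 7 lists in indoor against untreated cells that were not called over all arrays. Higher were aryl hydrocarbon receptor targets (adjusted p = 8.4e-18, against 0.186 over all arrays), immediate early genes (6.64e-08, against 0.307), matrix proteases (0.000311), hypoxia (0.000572) and NRF2 targets (0.0326), and lower were DNA replication (0.00931) and oxidative phosphorylation (0.0479). With outdoor particles, aryl hydrocarbon receptor targets were higher (0 called and 5 adjusted over the list alone, median 0.271, adjusted p = 1.67e-07, and adjusted p = 0.218 with an estimated correlation). NRF2 antioxidant targets were higher and hypoxia and glycolysis, DNA replication, and extracellular matrix and mesenchymal genes lower (adjusted p = 0.00718, 0.0012, 0.00339 and 0.00718, each adjusted p = 0.361 with an estimated correlation). Of these calls, hypoxia ended without the replicate 1 array labelled untreated (adjusted p = 0.55) and in replicates 2 and 3 alone (0.343), extracellular matrix without outdoor replicate 1 (0.0543) and in replicates 2 and 3 alone (0.0684), and NRF2 without outdoor replicate 1 (0.0777) or untreated replicate 3 (0.242). LOX, a collagen cross-linking enzyme, was at -0.38 and the microfibril gene FBN1 at -0.40. Between indoor and outdoor arrays, NF-kB cytokines (0 called and 7 adjusted over the list alone, median 0.229, adjusted p = 4.78e-14) and hypoxia genes (median 0.105, adjusted p = 5.4e-07) were higher, and aryl hydrocarbon receptor targets (median -0.204, adjusted p = 3.94e-05) and NRF2 targets (median -0.0504, adjusted p = 0.0232) lower. These had adjusted p = 0.262, 0.262, 0.262 and 0.43 with an estimated correlation. The aryl hydrocarbon receptor call ended in replicates 2 and 3 alone (adjusted p = 0.791), and without the replicate 1 array labelled indoor the list lay in the other direction (adjusted p = 0.559). Its adjusted p ranged from 8.19e-08 with an array left out to 0.791. The NRF2 call ended in replicates 2 and 3 alone (0.746) and without the replicate 1 array labelled indoor (0.825) or outdoor replicate 1 (0.152). Replicates 2 and 3 alone called immediate early genes (2.36e-05), matrix proteases (0.00906) and complement (0.0121) higher on indoor than on outdoor arrays. Extracellular matrix, complement and leukocyte and endothelial lists were not called between indoor and outdoor arrays (adjusted p = 0.123, 0.092 and 0.0823) and passed at adjusted p = 0.0375 each with a replicate block.

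Averaging the contrasts over the 3 times set 9 arrays against 9. It was chosen after genes such as CYP1A1 were seen to be high at each time without passing at any. The genes named here were also chosen after their values were seen, apart from those among the 16 genes fixed in advance. With outdoor particles 12 genes were called, 10 higher and 2 lower (limma, 912 at an unadjusted p under 0.05). CYP1A1 rose by 2.42 ± 0.323 (log2 ± SE, n = 9, adjusted p = 0.00065) and IL24 by 1.00 ± 0.198 (adjusted p = 0.0396). Further increases were those of CYP1B1 by 0.96 ± 0.146 (adjusted p = 0.00291), TIPARP by 0.94 ± 0.0957 (adjusted p = 1.09e-05) and the neuronal pentraxin NPTX1 by 0.92 (adjusted p = 0.00065). ARTN, the retinoic acid-forming ALDH1A3, CDX2, SLC7A5 and the thioredoxin reductase TXNRD1 rose by 0.41, 0.41, 0.33, 0.26 and 0.23. CLDN1, a tight junction protein, fell by -0.50 ± 0.0927 (adjusted p = 0.0258) and NREP by -0.24. CYP1A1, CYP1B1, TIPARP and NPTX1 passed under each of their 30 or 31 alternatives. The others did so less widely: ALDH1A3 in 27 of 31, CDX2 in 19 of 29, SLC7A5 in 18 of 31, CLDN1 in 17 of 29, ARTN in 16 of 30, NREP in 16 of 31, TXNRD1 in 15 of 31 and IL24 in 9 of 29. The count was 4 to 7 without any 1 of 10 arrays and 24 without untreated 24 h replicate 1. The aryl hydrocarbon receptor list had 4 of 9 members higher and 5 adjusted over the list alone (camera adjusted p = 2.2e-14, and adjusted p = 0.0187 with an estimated correlation), and DNA replication was lower (adjusted p = 5.59e-10, and adjusted p = 0.0484 with an estimated correlation).

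For indoor particles the mean over times gave 240 genes, 113 higher and 127 lower (limma, 2056 at an unadjusted p under 0.05). With 1 array left out the count ranged from 99 to 373, and with arrays centred on their medians most called genes were higher. CXCL1 rose by 1.76 ± 0.237 (log2 ± SE, n = 9, adjusted p = 0.000117), CYP1A1 by 1.65 ± 0.323 (adjusted p = 0.00809), CCL20 by 1.63 (adjusted p = 3.45e-06), CYP1B1 by 0.80 (adjusted p = 0.00396) and TIPARP by 0.79 (adjusted p = 5.84e-05). These means include the opposite pair of replicate 1 at 24 h: with replicates 2 and 3 alone there, CYP1A1 was at 2.20 with indoor and 2.66 with outdoor particles (adjusted p = 5.48e-08 and 8.47e-09) and CXCL1 at 2.21 with indoor particles. The difference in CYP1A1 between indoor and outdoor particles was -0.76 with all arrays and -0.46 without replicate 1 at 24 h (adjusted p = 0.542 and 0.61). SCEL, IFIT1 and TXNIP fell by -0.60, -0.50 and -0.44, SCEL passing under 16 of 30 alternatives. NF-kB cytokines had 24 of 32 members higher (camera adjusted p = 1.96e-43, and adjusted p = 0.00363 with an estimated correlation). Between indoor and outdoor particles 49 genes were called, 44 higher and 5 lower with indoor particles (933 at an unadjusted p under 0.05), led by CXCL1 at 2.02 (adjusted p = 1.8e-05) and CXCL8 at 1.78 (adjusted p = 1.34e-06), with CLDN1 higher by 0.76 (adjusted p = 2.93e-05). The count of 49 ranged from 33 to 82 with 1 array left out.

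The change of each response with time was tested directly. CCL20 (3.23 at 4 h, 1.32 at 10 h and 0.35 at 24 h, adjusted p = 0.00519), the Eph receptor ligand EFNA1 (0.74, 0.09 and -0.08, adjusted p = 0.0108) and TNFAIP2, a TNF-induced gene (1.15, 0.36 and 0.02, adjusted p = 0.0108), changed with time in the indoor response by limma's moderated F test; 1149 genes had an unadjusted p under 0.05. These 3, and SIRT5 in the test of indoor against outdoor, are the genes called, named after their values were seen. With 1 array left out the count of 3 ranged from 0 to 7, and 8 of 100 splits of the same arrays called at least as many. The 24 h values included the opposite pair of replicate 1. CCL20 at 24 h was at 1.06 in replicates 2 and 3 and at -1.07 in replicate 1. With replicates 2 and 3 alone at 24 h its change with time had adjusted p = 0.000381, and EFNA1 and TNFAIP2, at 0.04 and -0.02 at 24 h, had adjusted p = 0.0268 each. TNFAIP3, ICAM1, PTX3 and RELB then passed as well, at 1.19, 0.66, 0.89 and 0.71 at 24 h. Their values were 2.14, 1.34, 2.44 and 0.97 at 4 h and 1.04, 0.54, 1.18 and 0.0965 at 10 h. All but PTX3 were thus lowest at 10 h, where the arrays carried the 3' excess of beta-actin. The outdoor response gave 0 such genes (517 at an unadjusted p under 0.05, smallest adjusted p 0.468), and the difference between indoor and outdoor gave 4, CCL20, EFNA1, TNFAIP2 and the desuccinylase SIRT5 (-0.02, -0.43 and 0.20, adjusted p = 0.0452). With replicates 2 and 3 alone at 24 h it gave 8, and TNFAIP2 (adjusted p = 0.0769) and SIRT5 (adjusted p = 0.131) did not pass. The inflammatory list fell between 4 h and 24 h in the indoor response (median -0.859, camera adjusted p = 2.1e-34, and adjusted p = 0.0115 with an estimated correlation). With replicates 2 and 3 alone at 24 h the median was -0.421 (camera adjusted p = 2.68e-23, and adjusted p = 1.47e-07 with an estimated correlation). Of the 63 genes higher with indoor particles at 4 h, 58 lay in the same direction at 10 h with a median of 0.434 and 55 at 24 h with a median of 0.15. Within series at 24 h, 59 lay in the same direction in replicates 2 and 3 with a median of 0.405, and 6 in replicate 1 with a median of -0.33. At both 4 h and 10 h 23 were called higher, where independent lists would share 0.743. In untreated cells alone 6327 genes (52.9%) differed over the 3 times, where time and array series cannot be told apart.

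The indoor and outdoor responses were compared over all genes. Their log2 fold changes correlated at r = 0.676 at 4 h, 0.432 at 10 h and 0.506 at 24 h across genes, which are not independent replicates. Unchanged groups simulated against the same untreated arrays gave mean values of 0.403, 0.437 and 0.441, over ranges of -0.371 to 0.953, -0.491 to 0.977 and -0.748 to 0.963. The covariance was 0.0154, 0.0113 and 0.00525, against simulated means of 0.00527, 0.00975 and 0.00476 (differences 0.0102, 0.00154 and 0.000498) and highest simulated values of 0.023, 0.0502 and 0.022. The observed correlations and covariances thus lay within what the shared untreated arrays gave without any response. TIPARP was the only gene called with both particles, at 4 h, where independent lists would share 0.00527 genes. The numbers at 10 h and 24 h were 0, since outdoor particles gave no called gene there. Unchanged groups simulated against the same untreated arrays shared 0, 17.9 and 0.94 called genes on average at 4, 10 and 24 h. Genes can thus be called at 10 h without any response. With 3 untreated arrays per time the controls could not be split, and part of any excess may come from them. The 63 genes higher with indoor particles at 4 h had a median of 0.129 with outdoor particles against 0.90 with indoor particles, 52 of them above untreated.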

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

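The beta-actin covariate, the check of RNA ends in outdoor arrays at 4 h, the test between array series, the mean over times, the comparison of spread at 24 h, the exchange of labels in the inflammatory genes and the change from 4 h to 24 h as a contrast, with all arrays or with replicates 2 and 3 alone, were tests chosen after the results were seen.

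Some responses differed between times in a test of the difference itself. In indoor against untreated cells these were CCL20 (adjusted p = 0.00519), EFNA1 (adjusted p = 0.0108) and TNFAIP2 (adjusted p = 0.0108), each larger at 4 h than later by limma's F test. Between indoor and outdoor particles they were EFNA1 (adjusted p = 0.021), TNFAIP2 (adjusted p = 0.0396), CCL20 (adjusted p = 0.0396) and SIRT5 (adjusted p = 0.0452). Both sets of calls depended on single arrays: with 1 left out, the counts of 3 and 4 ranged from 0 to 7 and from 0 to 22. The inflammatory list was lower at 24 h than at 4 h in indoor against untreated (camera adjusted p = 2.1e-34, and adjusted p = 0.0115 with an estimated correlation) and in indoor against outdoor (camera adjusted p = 3.47e-34, and adjusted p = 0.0119 with an estimated correlation). At 24 h the response differed between the 2 array series for 32 genes in indoor against untreated, 2 in outdoor against untreated and 3 in indoor against outdoor, in a test that rests on 1 array per group in replicate 1 and takes its spread from the other groups. The 3151 probe sets that name no single gene entered none of the main gene counts. In the fit of all probe sets that were not controls, 12 of them were called for indoor against untreated and 6 for indoor against outdoor at 4 h, and 61 and 33 at 10 h.

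The 203 genes lower and 141 genes higher with indoor particles at 10 h lay on arrays that had lost 5' signal; with the beta-actin end difference as a covariate, the median change was 0.972 of its size for the lower genes (-0.443 to -0.431, median SE 0.106 to 0.111) and 0.958 for the higher genes (0.437 to 0.419, SE 0.104 to 0.109), while 81 and 46 stayed called. Both parts of that fit ended calls, since 97 and 63 passed with its standard errors and degrees of freedom alone and 156 and 97 with its folds alone. The covariate came from beta-actin only. GAPDH, whose mean end difference at 10 h was 1.05 in indoor and 0.758 in untreated arrays, was not fitted. Without indoor replicate 2 the lower genes kept 0.92 of their median change (-0.408, SE 0.114), with 35 called. That share cannot decide whether the array was the source, because the genes were called with it included. Of the 203, 199 had every indoor array below every untreated one, so the remaining arrays were bound to keep much of the change. Over all genes the count fell from 344 to 71 without that array. If the lower genes were ones that lose signal with 5' ends, they should lose it at 10 h in outdoor arrays too, but there they gained 0.486 over the other times, at percentile 100 of 10000 matched random lists (-0.00621 to 0.123), opposite to that loss and also outside the range set beforehand for no effect, so that they stood apart at 10 h. A response to indoor particles, and a difference tied to what sets the 10 h arrays apart, where time and array series cannot be told apart, both may contribute.

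The inflammatory genes higher with indoor particles at 4 h could come from leukocyte RNA only if leukocyte genes rose with them. The leukocyte and endothelial list had a median of 0.038, against 1.11 for the inflammatory list, and PTPRC was at 3.12 in both groups. The upper 95% bootstrap bound of the leukocyte median was 0.154, drawn over 17 genes and not over arrays. A difference in RNA ends was checked by beta-actin in the outdoor arrays. Their end difference exceeded that of untreated arrays by 0.12, against 0.0745 for indoor arrays (exact permutation p = 0.3 and 0.4, each within the spread of the arrays), while the list's median was 0.0898 with outdoor particles. By GAPDH the order turned, with means of -0.0492 in indoor, -0.0619 in outdoor and -0.0937 in untreated arrays at 4 h. The check needs outdoor arrays to differ at least as much as indoor ones, and with that order unsettled it decides nothing. The beta-actin covariate, with 0.972 of the median left (1.11 to 1.08), decided nothing at 4 h, where it had little to correct. A response of the epithelial cells to indoor particles stays open as a hypothesis, and soluble contents of the particles were not tested apart.

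The absence of called genes at 24 h went with a larger spread in the inflammatory list, whose median SD within groups was 1.86 times that at 4 h, or 0.812 times in replicates 2 and 3 alone, and not with a larger spread over all genes (0.868 times). The inflammatory response was also smaller at 24 h than at 4 h, by a median of -0.859 with all arrays (camera adjusted p = 2.1e-34, 9.11e-36 before adjustment) and -0.421 with replicates 2 and 3 alone at 24 h (adjusted p = 2.68e-23, 1.16e-24 before adjustment). A candidate explanation for the spread is an exchange of the labels of the indoor and untreated arrays of replicate 1: the labels as given called 0 genes and the split of the arrays that exchanges this pair called 37, and in the pair the median of indoor minus untreated was -1.18 for CYP1A1, CYP1B1 and TIPARP and -0.529 for the inflammatory list, opposite to replicates 2 and 3. Against the outdoor array of its series the array labelled indoor lay where untreated lay in replicates 2 and 3 (CYP1A1 -3.17 and -3.28), and the array labelled untreated nearer to where indoor lay (CYP1A1 -1.07 and -0.46, CXCL1 1.78 and 2.09). An exchange may thus account for this pair, but these are single arrays of another array series, a different response there was not excluded, and the labels were kept.

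Other splits of the same arrays were fitted to see how many genes they call. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. At 4 h the real split called 77, 1 and 36 genes for indoor against untreated, outdoor against untreated and indoor against outdoor, and the highest of the others 0, 0 and 0, so that 1 of 10 splits reached the real count in each. At 10 h the real counts were 344, 0 and 186 and the highest others 7, 22 and 70, with 1, 10 and 1 of the splits reaching them. At 24 h the real counts were 0, 0 and 0 and the highest others 37, 1 and 0, with all 10 splits reaching them. The split with 37 sets the replicate 1 array labelled indoor with untreated replicates 2 and 3, which is the exchanged labelling of that pair; the split with 22 at 10 h points to a structure of those arrays.

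For the mean over the 3 times, 100 splits were drawn. The real counts of 240, 12 and 49 genes were reached by 2, 1 and 1 of them, with highest others of 269, 5 and 26. Few splits thus reached these counts, and the real split was among the 100. The contrast was itself chosen after the values were seen, which the splits do not allow for, so chance is not excluded. The split with 269 genes, above the real 240, moves indoor replicates 1 and 3 at 24 h and points to a structure of those arrays. The counts that changed with time, 3, 0 and 4, were reached by 8, 100 and 8 of 100 splits (highest others 76, 5 and 32), so chance cannot be excluded for them, and splits with many times the real count point to a structure of the arrays. For untreated cells across time 6327 genes were reached by the real split alone, 1 of 100 (highest other 5493).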

How the results depend on the processing

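The main model and most alternatives were set before the data were examined. The beta-actin covariate, leaving out the 10 h arrays and 24 h against 4 h alone were chosen after the data were seen. So were the mean over times and replicates 2 and 3 alone, outside the 24 h comparisons for genes and throughout for lists. Counts are given in the order indoor against untreated, outdoor against untreated, indoor against outdoor. The robust prior and leaving out genes below the median moved no count by over 1.5 times, nor did centring the arrays. Except for the beta-actin covariate with indoor particles at 10 h, and where an alternative tests or fits fewer arrays or adds a fold minimum, the cause was not tested.

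At 4 h (77, 1 and 36 genes) array weights gave 838, 2 and 72; the 1.5-fold minimum gave 51 for the first, and replicates 2 and 3 alone at 24 h gave 8 and each time alone 5 for the second. At 10 h (344, 0 and 186) the series term left out gave 172 for the first and 78 for the third, each time alone 34, 4 and 11, array weights 23 and 0 for the first and the third, the 1.5-fold minimum 60 and 32, and the beta-actin covariate 142, 2 and 5, with 127 of the 344 genes kept. Replicates 2 and 3 alone at 24 h gave 8, every probe set 1 and quantile normalization 3 for outdoor particles at 10 h. At 24 h (0, 0 and 0) replicates 2 and 3 alone gave 26, 5 and 10, and array weights 3 and 2 for the second and the third. For change with time (3, 0 and 4), replicates 2 and 3 alone at 24 h gave 7 and 8 for the first and the third; for the first an intensity trend gave 5, array weights 6, leaving out genes below the 40th percentile 6, every probe set 6 and 24 h against 4 h 5; for the second every probe set gave 1; for the third no series term 0, the mean of probe sets 1, every probe set 0 and 24 h against 4 h without the 10 h arrays 2. For the mean over times (240, 12 and 49), no series term gave 139 and 7 for the first and second, array weights 583 and 83 for the first and the third, and replicates 2 and 3 alone 19 and every probe set 20 for the second. Genes called with both particles rose from 0 to 2 at 10 h with quantile normalization. Centring moved the share of higher genes for the mean of indoor against untreated from 47.1% to 60.4%.

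With the replicate number as a block, counts were 122 and 3 for indoor and outdoor particles at 4 h, 7 for outdoor particles and 293 for indoor against outdoor at 10 h, 8 and 7 for change with time of indoor against untreated and indoor against outdoor, and 27 for the mean of outdoor particles; genes called with both particles were 3 at 4 h and 4 at 10 h. As a random block (consensus correlation 0.0594) it gave 2 for outdoor particles and 284 for indoor against outdoor at 10 h. Where the numbers pair the arrays, the block gave 472 genes for indoor against untreated at 10 h and 0 at 24 h, and changed no other call than those given with the results and MAFG at 10 h (adjusted p = 0.0536). In the contrasts without pairing, at least 1 number correlated under 0.1, down to -0.094.

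Leaving out 1 array in turn gave 33 to 333, 1 to 30 and 22 to 37 genes at 4 h, 71 to 546, 0 to 24 and 21 to 588 at 10 h, and 0 to 7, 0 to 5 and 0 to 12 at 24 h. It gave 0 to 7, 0 to 0 and 0 to 22 for change with time, 99 to 373, 4 to 24 and 33 to 82 for the mean over times, and 5771 to 6335 for untreated cells across time. For indoor against untreated, change with time fell to 0 without untreated 4 h replicate 2 and to 1 without untreated 4 h replicate 3 or indoor 4 h replicate 1, and rose to 5 without indoor 24 h replicate 3 or untreated 24 h replicate 2 and to 7 without indoor 24 h replicate 1. For indoor against outdoor it was 0 without indoor 4 h replicates 1 or 3, outdoor 4 h replicates 2 or 3 or outdoor 24 h replicates 1 or 2, 1 without outdoor 10 h replicate 1 or outdoor 24 h replicate 3, 2 without indoor 4 h replicate 2 or indoor 24 h replicates 2 or 3, 7 without indoor 24 h replicate 1 and 22 without indoor 10 h replicate 3. The mean for indoor particles was 99, 129, 110 and 141 without indoor 24 h replicates 3 and 2 and untreated 24 h replicates 2 and 3, 127, 133, 135 and 153 without untreated 4 h replicate 2, indoor 4 h replicates 2 and 3 and indoor 10 h replicate 2, and 370 and 373 without untreated 4 h replicate 1 and indoor 10 h replicate 1. The mean for outdoor particles was 4 to 7 without outdoor 4 h replicates 1 or 2, untreated 4 h replicate 2, untreated 10 h replicate 3, outdoor 10 h replicates 1 or 2, untreated 24 h replicates 2 or 3 or outdoor 24 h replicates 1 or 3, and 24 without untreated 24 h replicate 1. For indoor against outdoor it was 82 without indoor 24 h replicate 1.

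Of 59 lists called by camera, 5 held with an estimated correlation and 13 with fry, and 76 refits of called lists without 1 array lost the call, while 51 refits of other lists gained one. Leaving out genes below the 40th percentile ended 9 calls and gave 13, replicates 2 and 3 alone at 24 h ended 8 and gave 12, the beta-actin covariate ended 3 and gave 5, centring ended 4, no series term ended 3 and gave 1, and the replicate block ended 1 (NRF2 targets, outdoor particles at 10 h, adjusted p = 0.056) and gave 5. Lists whose direction reversed were all at 24 h. The inflammatory list in outdoor against untreated (adjusted p = 0.0982, lower) was higher in replicates 2 and 3 alone (0.00129) and without untreated replicate 1 (5.16e-10; 5.16e-10 to 0.222 over arrays left out), and immediate early genes there (0.938) without the same array (0.00575; up to 0.986). The aryl hydrocarbon receptor list in indoor against outdoor (3.94e-05, lower) lay the other way without indoor replicate 1 (0.559; from 8.19e-08). Of 127 calls of named genes, 43 were lost with the beta-actin covariate and 53 with array weights, and none reversed in any alternative. No measure of signal over background was used here, so what dim signal limits was looked at only by leaving out dim genes. A gene below a cut was absent from that refit, so passing under each of its alternatives does not cover dim signal.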

Other observations

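The test of the mean over times and the look at CLDN1 were chosen after the results were seen. CYP1A1, CYP1B1 and TIPARP, targets of the aryl hydrocarbon receptor, lay above untreated with both kinds of particle, while the inflammatory genes lay far higher with indoor ones. In the mean over times CYP1A1 was at 1.65 for indoor and 2.42 for outdoor particles (limma, adjusted p = 0.00809 and 0.00065), or 2.20 and 2.66 with replicates 2 and 3 alone at 24 h, and 6 of 6 tests passed over the 3 genes and both particles. That leaves undecided the hypothesis of a response that both kinds of particle share over the 3 times. The 3 genes were among those fixed in advance, but they and the mean were picked for this test for being high. A mean over times also does not show a response at each. The comparisons share their untreated arrays, so part of the likeness may come from those. Whether the list's response to outdoor particles was smaller at 24 h than at 4 h stayed undecided (median -0.0194, camera adjusted p = 0.366, 0.164 before adjustment), and with replicates 2 and 3 alone at 24 h the sign turned (median 0.0104, adjusted p = 0.865, 0.715 before adjustment). A value of 0.05 or more had been set beforehand as evidence against a decrease, wrongly, since missing the threshold excludes nothing.

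CLDN1, a tight junction protein named after its values were seen, moved differently with the 2 kinds of particle. At 4 h it was higher by 0.79 ± 0.161 with indoor particles than in untreated cells (log2 ± SE, n = 3; limma, adjusted p = 0.0141) and at -0.45 ± 0.161 with outdoor particles (adjusted p = 0.825), a difference of 1.24 between the particles (adjusted p = 0.000102). In the mean over times, the difference between particles passed under each of 29 alternatives, and the decrease of -0.50 with outdoor particles under 17 of 29.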
